A study of Mus musculus with 10 samples.

How the data were processed

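Total RNA from the aorta of male mice, wild type on 5 arrays and Npas2 mutant on 5, was biotin-labelled and hybridised to Affymetrix MOE 430V2 arrays, a mouse whole-genome platform, per the labels. The authors deposited log2 expression values, a single value per probe set and array, already summarised over probes and normalised between arrays. The submitters' processing notes name GCRMA and MAS5, with no version and no statement of which made the table. The scale was read from the values, which lay between 1.10 and 14.74 and had upper quartiles per array between 5.40 and 5.55, as log2 values would and linear MAS5 signals would not. Dates of hybridisation or scanning are not given in the sources used here, so batches could not be examined. The labels give each replicate its own identifier, shared by no array of the other group, so no pairing was used.

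The table held 45101 probe sets, of which 64 were controls and 45037 were not. The platform's annotation, which is old, gave 34958 probe sets a single gene, 932 several genes and 9160 no gene, and a probe set it does not list is unnamed here. The counts with a gene cover the whole table, controls included, while the count with no gene leaves controls out. Symbols were updated by gene identifier to the names of the mouse assembly GRCm38.p6, which succeeded for 34754 of the 34958 probe sets. Gene positions of that assembly served to find which genes neighbour Npas2, and no coordinates are given. No gene was named from a probe set with several genes.

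The deposited values were used as given, with no further normalisation in the main setting. Probe sets were tested if they were above their own array's median on at least 5 of the 10 arrays, which left 22340 probe sets and 10945 genes. The contrast was mutant minus wild type, fitted with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Standard errors are the moderated ones of that fit, and SD values are plain standard deviations over the 5 arrays of a group. For dim or single quantities exact two-sided permutation tests over all splits of 5 against 5 were used, whose smallest possible p is 0.00794.

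Before the data were examined, 29 gene lists were fixed from textbook knowledge, covering the clock, the cell types an aortic sample could hold, and general pathways. They were core clock, clock output, contractile smooth muscle, extracellular matrix, endothelial, adventitial fibroblast, adipocyte, brown fat, skeletal muscle, cardiac muscle, macrophage and leukocyte, lymphocyte, erythroid, nerve and Schwann, adrenergic and vasoactive, coagulation and fibrinolysis, immediate early, heat shock and protein folding, glucocorticoid response, fatty acid oxidation, oxidative phosphorylation, cholesterol and fatty acid synthesis, interferon response, inflammation, cell cycle, haem metabolism, hypoxia and glycolysis, ribosomal proteins and proteasome. Each gene entered with its brightest tested probe set. The 27 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists, which compares a list with the other genes. An estimated correlation and fry, which tests whether the members move on balance 1 way without comparing them with other genes, were alternatives. A call adjusted over the list alone used the members' own p values. Of the 14 brown fat genes 1 is also in another list.

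The naming rule, also fixed before, took every Npas2 probe set, the 12 called genes with the largest rise and the 12 with the largest fall (1 probe set per gene, the largest change). It also took every measured core clock gene, the called members of each list (at most 4) or else the 2 members of largest change, Nnt, and Xist and Y-linked genes as a check of the sex label.

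The tests were tried on simulated data of 5 against 5 arrays over 22340 probe sets, with the means and spreads of the real ones. Each probe set was drawn independently, so the correlation between probe sets that the real arrays hold was left out. Of 100 probe sets changed by 0.5 on the log2 scale 40 were recovered, and of 100 changed by 1 all but 8 were, that is 92. Of 142 calls 10 were false and 0 had the wrong sign. With no change simulated 0 probe sets were called.

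Alternatives were the filter on dim probe sets (none, or the 75th percentile), quantile normalisation and median centring, the variance model, array weights and an ordinary one-way analysis per probe set as the series design names it. Further ones were other thresholds, leaving out probe sets with the suffix _x_at or _s_at, leaving out each array in turn, adipocyte and skeletal muscle list means as covariates, and leaving out genes within 20 Mb of Npas2. A brown fat covariate and leaving out the 4 arrays with most skeletal muscle signal were added after the data were seen. Nothing was left out of the main comparison apart from control and dim probe sets.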

Results

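Transcript levels were measured in the aorta of male mice carrying a mutation in Npas2 and of male wild-type mice. Npas2 encodes a transcription factor of the circadian clock, a paralogue of Clock that pairs with the protein made from Arntl (also called Bmal1). Per the labels, every mouse was killed at zeitgeber time 14 h, after at least 2 weeks under 12 h of light and 12 h of darkness and then at least 30 h of constant darkness. Each group held 5 arrays, 10 in all, and each array was 1 replicate. The labels do not say whether each array held RNA of a separate mouse, so the p values measure the spread between these arrays. The labels put the tissue down as thoracic aorta in 1 place and as a longer piece, from the arch past the femoral branching, in another. The labels name C57Bl/6 as the strain of the wild-type mice and C57Bl/6J as the background of the mutants. The series design names a single contrast, strain, and the question addressed was which transcripts differed in abundance between mutant and wild-type aorta. The upper quartile of the levels lay between 5.40 and 5.55 on the log2 scale on every array, and the number of arrays limits the precision. No pair of arrays held identical values, and correlations across probe sets ranged from 0.988 to 0.996 within groups and from 0.986 to 0.996 between groups. The levels of Xist and of Y-linked genes matched the male label on all 10 arrays.

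The targeted gene was examined first. Npas2 was near the lower end of the array's range in both groups. Its brighter probe set, 1421037_at, had a log2 level of 3.71 ± 0.24 (SD, n = 5) in wild type and 3.43 ± 0.03 (SD, n = 5) in the mutant. The log2 change was -0.28 ± 0.10 (SE), with all 5 mutant arrays below the wild-type mean. The limma adjusted p over all tested probe sets was 0.249, so Npas2 did not pass that test. Taken alone, this probe set had an unadjusted limma p of 0.0225 and an exact two-sided permutation p of 0.0238, and the groups overlapped. The other probe set, 1421036_at, stood at 2.37 ± 0.09 and 2.38 ± 0.08 (SD, n = 5 each), too dim to be tested with the rest, and an exact two-sided permutation test of its difference gave p = 0.833. Neither the nature of the mutation nor the part of the transcript that these probe sets read is given in the sources used here. The Npas2 signal therefore does not check the genotype labels in either direction.

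A small set of genes separated mutant from wild-type aorta. Cyp2b10, a cytochrome P450 of drug and steroid metabolism, rose 4.60-fold in the mutant, a log2 change of 2.20 ± 0.34 (SE, n = 5 per group). Acaa1b, Ehhadh, Ephx2 and Hacd2, which encode enzymes acting on fatty acids, rose as well. Among the genes that fell were Id4 and Smad6, which encode inhibitors of transcriptional signalling, and Rgs5, a regulator of G protein signalling in vascular mural cells. The deepest fall, 5.17-fold, was in Pisd-ps3, a pseudogene of the phosphatidylserine decarboxylase gene. In all, 48 of 22340 tested probe sets passed a limma adjusted p of 0.05, 21 of them higher and 27 lower in the mutant. They named 30 genes, 16 that rose and 14 that fell, while 8 of the probe sets had no gene name and 2 named several genes. Their absolute log2 changes ran from 0.36 to 2.37. On all 48 the 5 mutant arrays did not overlap the 5 wild-type arrays. Among all tested probe sets 895, or 4.01%, showed such separation, where chance gives 0.794%. At an unadjusted p of 0.05, 3427 probe sets passed, where 1117 are expected by chance. The count rested on the choice of arrays: it was 34 without wild type F11 and 43 without wild type F14_2, but between 9 (without wild type F16) and 23 (without mutant F18) when any of the other 8 arrays was left out. Centring each array on its median turned the split from 21 higher and 27 lower to 34 higher and 18 lower. A skeletal muscle marker score as a covariate left 7 probe sets. The 48 changes kept their size (median ratio 0.9996) and all 48 had an unadjusted limma p under 0.05. That was largely fixed in advance, because the 48 were picked on these arrays for separating the groups. The score correlated with group at 0.287.

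Several of the genes that rose encode enzymes of lipid or xenobiotic metabolism. For Cyp2b10 (probe set 1422257_s_at) the mean log2 level was 4.42 ± 0.62 (SD, n = 5) in wild type and 6.62 ± 0.62 (SD, n = 5) in the mutant, with a limma adjusted p of 0.0349. Its other called probe set rose by 2.11, and 1451787_at, which did not pass, had a change of 2.02 (adjusted p = 0.0930). Both called probe sets carry a suffix that marks probes shared with related transcripts, so other members of the Cyp2b family may add to the signal. Acaa1b, a peroxisomal thiolase that cleaves 3-ketoacyl-CoA, rose by 1.08 ± 0.16 (SE) and Ehhadh, the peroxisomal bifunctional enzyme, by 0.81 ± 0.13. Apoc1, an apolipoprotein of triglyceride-rich lipoproteins and high-density lipoprotein, rose by 0.85 ± 0.12. Hacd2, a dehydratase of very long chain fatty acid elongation, rose by 0.68 ± 0.10, and Ephx2, the soluble epoxide hydrolase that breaks down epoxyeicosatrienoic acids, rose by 0.54 ± 0.08. The adjusted p of these 5 genes lay between 0.0306 and 0.0438, with all 5 mutant arrays above the wild-type mean for each. The mean of the brown fat marker list was also higher in the mutant, at 9.08 ± 0.26 (SD, n = 5) against 8.48 ± 0.20 (SD, n = 5). With that mean as a covariate, added after the data were seen, the changes were 1.48 ± 0.57 (SE) for Cyp2b10, 0.55 ± 0.22 for Acaa1b and 0.46 ± 0.16 for Apoc1, but 0.95 ± 0.24 for Ehhadh. Of the 21 probe sets that rose, 17 had a smaller and 4 a larger change with this covariate, and none of the named genes passed any longer, with wider standard errors because the covariate itself does not overlap between the groups.

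The other genes that rose had varied functions. Tuba8, an alpha tubulin, rose by 1.05 ± 0.16 (SE) and Rbm47, an RNA-binding protein, by 0.84 ± 0.11, while a second probe set of each, at 0.75 (adjusted p = 0.186) and 0.60 (adjusted p = 0.114), did not pass. Slc4a4, the electrogenic sodium bicarbonate cotransporter, rose by 0.80 ± 0.13 on probe set 1434096_at and by 0.74 ± 0.10 on probe set 1426432_a_at. Tmed5, a member of the p24 family of vesicle cargo receptors, rose by 0.73 ± 0.11 on 1424574_at and Ppa1, an inorganic pyrophosphatase, by 0.64 ± 0.10. With the brown fat covariate the changes of Slc4a4 were 0.38 ± 0.17 (SE, 1434096_at) and 0.43 ± 0.14 (1426432_a_at), while that of Ppa1 was larger, at 0.80 ± 0.17. Tmed5 was also called on a further probe set, 1424573_at, at 0.69 ± 0.07 (SE, limma adjusted p = 0.00721). On the other called probe sets of these 5 genes the limma adjusted p lay between 0.0255 and 0.0387. Hspa5, the chaperone of the endoplasmic reticulum also called BiP, was called on the dim probe set 1447824_x_at alone, with a log2 change of 0.71 ± 0.11. Its bright probe sets disagreed with that, at 0.09 (1416064_a_at, adjusted p = 0.762) and 0.23 (1427464_s_at, adjusted p = 0.403). Outside the naming rule, and named after their values were seen, Ddt (0.42), Acad11 (0.42) and Scarb2 (0.37) were also called higher. Hspe1, the mitochondrial co-chaperonin, rose by 0.38 ± 0.06 (SE) and is the 1 called gene within 20 Mb of Npas2. That was on 1450668_s_at, and its other tested probe set, 1422579_at, had a change of 0.11 (adjusted p = 0.405).

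The genes that fell included regulators of signalling and proteins of the cell surface. Id4, an inhibitor of basic helix-loop-helix transcription factors, fell by 0.73 on the log2 scale (SE 0.08, limma adjusted p = 0.00721), and 3 of its probe sets were called. Smad6, an inhibitory Smad of bone morphogenetic protein signalling, fell by 0.75 (SE 0.10, limma adjusted p = 0.0255). Fgfr2, a fibroblast growth factor receptor, fell by 0.61, Neo1, a receptor of the netrin and repulsive guidance molecule families, by 0.76, and Vasn, a transmembrane protein that binds transforming growth factor beta, by 0.44. Their adjusted p values lay between 0.0306 and 0.0320. The 3 other tested probe sets of Neo1, the brightest included, had changes between -0.39 and -0.24 and did not pass, nor did the brighter probe set of Fgfr2 (-0.37, adjusted p = 0.182). Dsp, the desmosomal protein desmoplakin, fell by 0.58 (adjusted p = 0.0373) and Slc26a2, a sulfate transporter, by 0.59 (adjusted p = 0.00721), while a dimmer Slc26a2 probe set had a change of -0.15 (adjusted p = 0.595). Rgs5 fell by 0.54 on probe set 1420940_x_at (SE 0.06, adjusted p = 0.00721) and by 0.39 on a second called probe set, 1420941_at. Its brightest probe set, 1417466_at, had a change of -0.37 with an adjusted p of 0.124.

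Pisd-ps3 (probe set 1453144_at) had a log2 level of 6.70 ± 0.45 (SD, n = 5) in wild type and 4.33 ± 0.47 (SD, n = 5) in the mutant, with a limma adjusted p of 0.00721. Its other 2 called probe sets fell by 1.95 and 1.88, and 2 that did not pass had changes of -0.66 and -0.48. A pair of probe sets that match both Pisd-ps1 and Pisd-ps3 fell by 0.77 and 0.75, so signal from near-identical copies of this pseudogene cannot be assigned to a single copy. Ctse, the aspartic protease cathepsin E, fell by 1.29 on probe set 1427797_s_at (adjusted p = 0.0387), while 1418989_at, its other tested probe set, had a change of 0.04. Gcn1, an activator of the amino acid sensing kinase Gcn2, fell by 0.72 and Lrrc17, a secreted leucine-rich repeat protein, by 0.45. Gpc6 (-0.36) and Zfp235 (-0.38) were also called lower and are named after their values were seen, being outside the naming rule. With the brown fat covariate, of the 27 probe sets that fell 15 had a smaller change, among them Dsp (-0.39 ± 0.15, SE) and Fgfr2 (-0.42 ± 0.15). The other 12 had a larger change, among them Pisd-ps3 (-3.02 ± 0.40, SE) and Smad6 (-1.004 ± 0.154), and none of the 27 passed. Id4, Pisd-ps3, Rgs5 and Slc26a2 passed the test in all 10 fits that left out an array. Smad6 passed in 6 and Rbm47 in 4 of these fits, Gcn1 and Hacd2 in 3 each, and the other named genes in 2 or fewer. Tmed5 was followed here on 1424574_at alone.

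**Figure D1:**
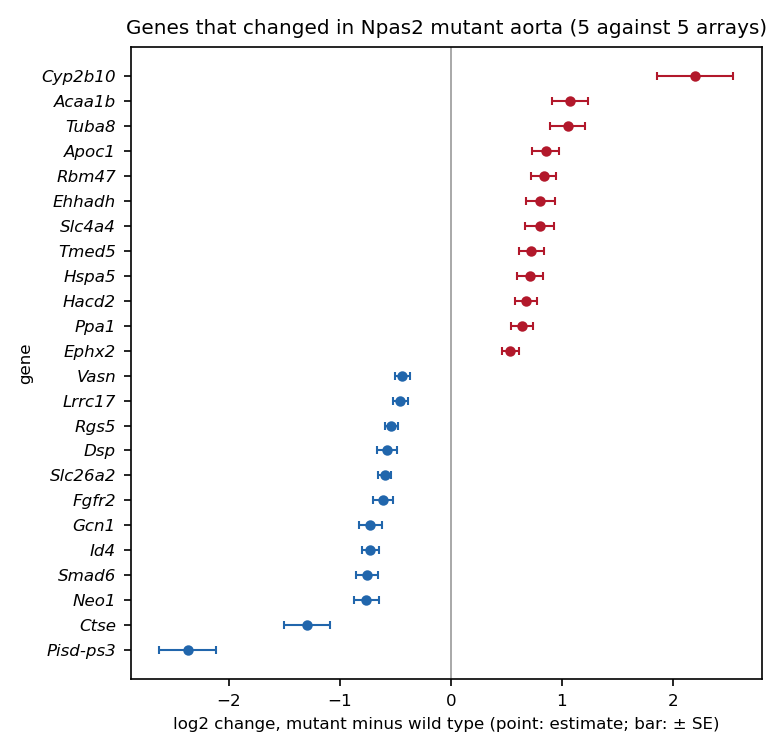
Log2 change, mutant minus wild type, of the 24 named genes that changed, with the standard error as bars (5 against 5 arrays). Cyp2b10 rose by 2.20 and Pisd-ps3 fell by 2.37, while the other genes lay between -1.29 and 1.08.

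Core clock genes were compared because Npas2 acts in the clock. At this single time point 15 of the 19 core clock genes were bright enough to test, and 0 passed the test over all probe sets (limma), with 5 at an unadjusted p of 0.05. Of the 15, 4 had a higher and 11 a lower mean in the mutant. Among the 4, Rorb (3.17 in wild type and 3.23 in the mutant) and Nr1d1 (3.36 and 3.46) were near the lower end of the range. Npas2 itself, also near that end, is in the list, as 1 of the 11 and 1 of the 5. Per1, a negative regulator of the clock, had log2 levels of 4.64 ± 0.04 (SD, n = 5) in wild type and 4.35 ± 0.14 (SD, n = 5) in the mutant, with no overlap of the groups. Its change of -0.28 ± 0.07 (SE) had a limma adjusted p of 0.125, and Per1 was the 1 gene that passed when adjusted over the list alone. The changes of Per2 (-0.16), Per3 (-0.30) and Cry2 (-0.24) and of the nuclear receptors Rora (-0.22) and Nr1d2 (-0.12) had adjusted p values between 0.205 and 0.589. So did Arntl2 (-0.13). These are values of the brightest probe set of each gene, and the 2 dimmer ones of Per2 had larger changes, -0.76 (1457350_at, adjusted p = 0.205) and -0.58 (1417603_at, adjusted p = 0.265). The kinase gene Csnk1e had a change of -0.24 (adjusted p = 0.184), and of -0.34 on 1417176_at (adjusted p = 0.139). Csnk1d had one of 0.13 on its brightest probe set (adjusted p = 0.589) and between -0.28 and -0.15 on the other 4, with adjusted p values from 0.136 to 0.433. Clock had a change of 0.15 ± 0.13 (SE), with other probe sets between -0.22 and 0.08. Cry1 (-0.03), Nr1d1 (0.10), Rorb (0.06) and the repressor gene Bhlhe40 (-0.21) had adjusted p values between 0.591 and 0.871. Arntl (0.44, exact permutation p = 0.0317), Ciart (0.27, exact permutation p = 0.190) and Bhlhe41 (-0.03, exact permutation p = 0.643) were too dim to be tested with the rest. The list had a median change of -0.16 and a camera adjusted p of 0.0977, and adjusted p = 0.699 with an estimated correlation. The list had a fry adjusted p of 0.146 for a shift 1 way and passed fry for a change in either direction (adjusted p = 0.0140). It passed camera without a filter on dim probe sets (adjusted p = 0.0303), with all probe sets of a gene averaged (adjusted p = 0.00838), without wild type F17 (adjusted p = 0.0345) and with the brown fat covariate (adjusted p = 0.0199). Its median change was -0.06 without mutant F20 (adjusted p = 0.239), -0.10 after median centring (adjusted p = 0.0726) and -0.04 without the 4 arrays rich in skeletal muscle signal (adjusted p = 0.417).

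Genes known as outputs of the clock went both ways. Of 16 measured members, 8 had a higher and 8 a lower mean in the mutant, with 0 called by limma over all probe sets, 0 adjusted over the list alone and 3 at an unadjusted p of 0.05. Pdk4, a kinase that restrains pyruvate oxidation, had a change of 0.57 ± 0.28 (SE, adjusted p = 0.364). Cdkn1a, a cell cycle inhibitor, had a change of 0.50 ± 0.15 (SE, adjusted p = 0.174). The camera adjusted p of the list was 0.955, with the test and the mean (0.00) above 0 and the median change below it (-0.05).

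**Figure D2:**
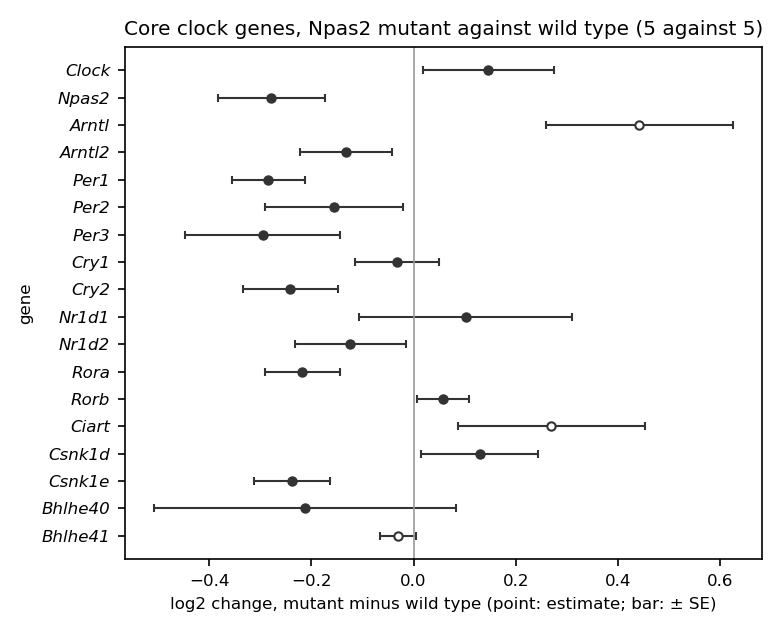
Log2 change, mutant minus wild type, of 18 core clock genes, with the standard error as bars (5 against 5 arrays) and open circles for genes too dim for the main test. Per1, at -0.28, was the gene whose groups did not overlap, and Arntl, at 0.44, was among the dim genes.

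Markers of brown fat and genes of fat oxidation were shifted upwards as groups by camera at its preset correlation, but not with a correlation estimated from the data (adjusted p = 0.699 for both) or by fry (adjusted p = 0.146 for both). Brown fat surrounds the thoracic aorta of the mouse. Ucp1, the uncoupling protein of brown adipocytes, had a log2 level of 11.42 ± 0.52 (SD, n = 5) in wild type and 12.42 ± 0.29 (SD, n = 5) in the mutant (limma adjusted p = 0.121). Elovl3, a fatty acid elongase of brown fat, stood at 4.15 ± 1.34 and 6.73 ± 0.66 (SD, n = 5 each), and its change of 2.57 ± 0.58 (SE) had an adjusted p of 0.111. Of 13 measured brown fat genes, 11 had a higher mean in the mutant, with 0 called over all probe sets by limma, 9 at an unadjusted p of 0.05 and 9 adjusted over the list alone, all higher, among them Slc27a2, Dio2, Cox8b and Cox7a1. At the preset correlation its camera adjusted p was 3.42e-06, and adjusted p = 0.699 with an estimated correlation. The list mean lay between 8.16 and 8.65 on the wild-type arrays and between 8.75 and 9.39 on the mutant arrays. An exact two-sided permutation test of the list mean gave p = 0.00794, the smallest that 5 against 5 arrays allow, and 0.230 after adjustment over 29 lists. No list that separates the groups alone could get a lower adjusted value, so that adjustment does not count against the separation.

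All 19 measured genes of fatty acid oxidation had a higher mean in the mutant. Ehhadh was the 1 member called over all probe sets, and 7 passed when adjusted over the list alone. These included the carnitine carrier Slc25a20 (0.52 ± 0.11, SE), the electron transfer dehydrogenase Etfdh (0.53 ± 0.14) and Acadm (0.36 ± 0.11), none of which passed over all probe sets. The camera adjusted p was 1.77e-10, and adjusted p = 0.699 with an estimated correlation. All 30 measured genes of oxidative phosphorylation also had a higher mean, with a median change of 0.22. Cycs, which encodes cytochrome c, had a change of 0.44 ± 0.12 (SE, adjusted p = 0.140) and Sdhd, a subunit of complex II, of 0.41 ± 0.16 (SE, adjusted p = 0.255). No member (0 of 30) was called by limma over all probe sets or adjusted over the list alone, and 13 passed an unadjusted p of 0.05. The camera adjusted p was 1.88e-11, and adjusted p = 0.773 with an estimated correlation. With the brown fat mean as a covariate, added after the data were seen, both lists turned, to a median change of -0.26 for fatty acid oxidation and -0.23 for oxidative phosphorylation. The brown fat list shares Cpt1b with the fatty acid oxidation list and holds the cytochrome oxidase genes Cox7a1 and Cox8b. Its mean correlated with group at 0.823, without overlap between the groups. The turn therefore does not decide whether brown fat content caused the higher means.

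White and general adipocyte markers did not pass camera in the main setting. Of 18 measured members 14 had a higher mean in the mutant, the median change was 0.10 and the camera adjusted p was 0.0582 (adjusted p = 0.813 with an estimated correlation). The list passed camera with the stricter filter on dim probe sets (adjusted p = 0.0340), with all probe sets of a gene averaged (adjusted p = 0.0212), and without wild type F14_2 or F15 or mutant F18 or F19 (adjusted p from 0.00474 to 0.0331). Its median change was smaller without wild type F11 (0.06) or mutant F13 (0.05), larger after median centring (0.16) and below 0 with the brown fat covariate (-0.19), and the list did not pass in these fits. Lep, the gene of the hormone leptin, had a change of -0.78 ± 0.22 (SE, adjusted p = 0.155) and Slc2a4, the insulin-responsive glucose transporter, of 0.39 ± 0.16 (SE, adjusted p = 0.281; 0.01 on its other probe set). Over all probe sets 0 members were called by limma, with 5 at an unadjusted p of 0.05, and 2 passed when adjusted over the list alone, Lpl (0.26) and Lep. Fabp4, a fatty acid carrier of adipocytes, was among the brightest transcripts, at 14.57 in wild type and 14.68 in the mutant.

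Contractile smooth muscle genes were shifted downwards as a group by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.773) or by fry (adjusted p = 0.219). Of 18 measured members 17 had a lower mean in the mutant, with a median change of -0.18, 0 called over all probe sets by limma, 8 at an unadjusted p of 0.05 and 6 adjusted over the list alone, all 6 lower. Tpm1, a tropomyosin, had a change of -0.36 ± 0.08 (SE, adjusted p = 0.121), and Cnn1, the calponin of contractile smooth muscle, of -0.26 ± 0.07 (SE, adjusted p = 0.164). Acta2, smooth muscle actin, had a change of -0.03 ± 0.06 (SE, adjusted p = 0.816). Des, the intermediate filament gene desmin, which skeletal muscle also expresses, was the 1 member with a higher mean, at 0.48 ± 0.40 (SE, adjusted p = 0.567). The camera adjusted p was 0.000169, and adjusted p = 0.773 with an estimated correlation. The brown fat mean, which was higher on all 5 mutant arrays, ended this call as a covariate (camera adjusted p = 0.193).

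Skeletal muscle transcripts differed more between single arrays than between the groups. The list mean was above 8 on 4 arrays, wild type F16 (9.36) and mutants F12 (10.49), F19 (8.53) and F20 (9.23), and lay between 3.56 and 6.07 on the other 6. All 17 measured members had a higher mean in the mutant, with 0 called by limma over all probe sets, adjusted over the list alone or at an unadjusted p of 0.05. Myh1, a fast myosin heavy chain, stood at 5.02 ± 2.11 and 7.93 ± 4.46 (SD, n = 5 each; adjusted p = 0.475) and Myh2, another, at 4.11 ± 1.54 and 6.79 ± 3.71 (adjusted p = 0.423). An exact permutation test of the list mean gave p = 0.421. The list passed camera (adjusted p = 0.00886), but adjusted p = 0.813 with an estimated correlation, and the call ended without wild type F11 or F17 or mutant F12, F19 or F20, where the adjusted p lay between 0.0770 and 0.238. The median change, 1.52 in the main setting, ran from 0.47 to 2.59 over the fits without 1 array. Leaving out the 4 arrays, a step added after the data were seen, left 4 wild-type and 2 mutant arrays and 0 called probe sets (limma), with 1549 at an unadjusted p of 0.05.

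**Figure D3:**
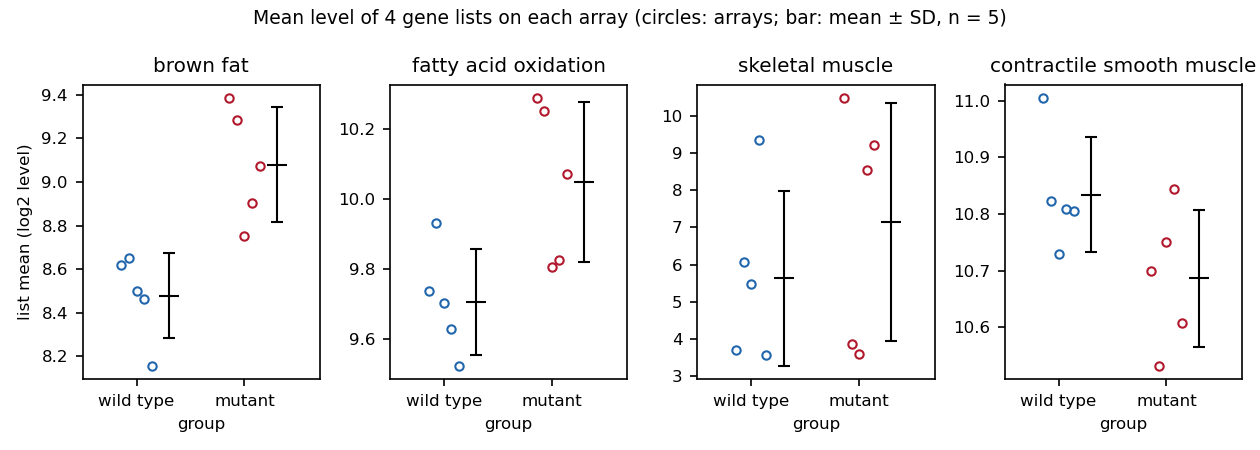
Mean log2 level of 4 gene lists on each of the 10 arrays (circles), with the group mean and SD as bars (n = 5). The brown fat mean separates the groups, at 8.16 to 8.65 in wild type and 8.75 to 9.39 in the mutant, while the skeletal muscle mean runs from 3.56 to 10.49 across both.

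Macrophage and leukocyte markers were shifted upwards as a group by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.699) or by fry (adjusted p = 0.247). Of 17 measured members 16 had a higher mean in the mutant, with a median change of 0.22 and 0 called by limma over all probe sets or adjusted over the list alone, against 5 at an unadjusted p of 0.05. Cd14, the endotoxin co-receptor of monocytes, had a change of 0.45 ± 0.13 (SE, adjusted p = 0.163) and Lyz2, a lysozyme of macrophages, of 0.36 ± 0.12 (SE, adjusted p = 0.212). The camera adjusted p was 1.27e-05, and adjusted p = 0.699 with an estimated correlation. The median change was 0.14 without wild type F14_2 (adjusted p = 0.00111) and 0.42 with the brown fat covariate (adjusted p = 4.55e-08). The lymphocyte list had 2 measured members, Ighm (0.38 ± 0.16, SE) and Ms4a1 (0.04 ± 0.07), and the erythroid list 3, including Slc4a1 (0.44 ± 0.31) and Alas2 (0.17 ± 0.45). Neither had enough members for camera, and exact two-sided permutation tests of the list means gave p = 0.0556 for the lymphocyte and p = 0.563 for the erythroid list.

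Genes of vascular tone were examined because the tissue is a large artery. Of 20 measured adrenergic and vasoactive genes 10 had a higher and 10 a lower mean, and camera gave an adjusted p of 0.369 (0.0450 without a filter on dim probe sets). With an estimated correlation in the main setting the camera adjusted p was 0.813. On the 1 probe set per gene used for lists 0 were called by limma over all probe sets and 4 passed an unadjusted p of 0.05, and 2 passed when adjusted over the list alone, Rgs5 and Gucy1a1. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, had a change of -0.38 ± 0.09 (SE, adjusted p = 0.122), and the groups did not overlap. In the coagulation and fibrinolysis list 5 of 10 had a higher mean, 0 were called, 2 passed an unadjusted p of 0.05 and 1 passed when adjusted over the list alone, Pros1 (-0.24 ± 0.05, SE, adjusted p = 0.119), the cofactor protein S. Tfpi, an inhibitor of the tissue factor pathway, had a change of 0.63 ± 0.25 (SE, adjusted p = 0.262), with its 3 other tested probe sets between -0.01 and 0.08. The camera adjusted p was 0.627.

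Structural cell types of the wall did not pass camera in the main setting. Endothelial markers had 10 of 17 higher means (adjusted p = 0.639), with opposite signs for the sialomucin Emcn (0.50 ± 0.14, SE, adjusted p = 0.164) and the adhesion molecule Pecam1 (-0.33 ± 0.12, SE, adjusted p = 0.220). Extracellular matrix genes had 8 of 22 higher means (adjusted p = 0.639), and the elastic fibre gene Fbln5 (-0.32 ± 0.10, SE) and the fibronectin gene Fn1 (-0.31 ± 0.13) did not pass. Adventitial fibroblast markers had 8 of 13 higher means (adjusted p = 0.997), with the median at 0.03 and the mean (-0.00) and the test pointing down. Their 2 members that passed over the list alone were Col14a1 (-0.27 ± 0.08, SE) and Mfap5 (-0.24), and Cd34 had a change of 0.29 ± 0.10. Nerve and Schwann cell genes had 8 of 11 higher means (adjusted p = 0.917), with Ncam1 at -0.33 ± 0.13 (SE) and Prph at 0.36 ± 0.61. Cardiac muscle genes had 3 of 7 higher means (adjusted p = 0.267), a median of -0.03 and a mean of 0.51, the latter set by Sln (1.92 ± 0.88, SE) and Myl3 (1.38 ± 0.54), which skeletal muscle also expresses. The cardiac list passed camera without mutant F13 (adjusted p = 0.0422) and with the adipocyte covariate (adjusted p = 0.0276). With the brown fat covariate the extracellular matrix and adventitial fibroblast lists passed upwards (adjusted p = 0.0199 and 0.000206), with medians of 0.10 against -0.07 and 0.28 against 0.03 without it. With an estimated correlation in the main setting the camera adjusted p was 0.813 (cardiac), 0.991 (matrix) and 0.999 (fibroblast). The 5 lists had 0 members called by limma over all probe sets, and at an unadjusted p of 0.05 there were 3 endothelial, 4 matrix, 3 fibroblast, 1 nerve and 1 cardiac gene.

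Stress and signalling lists did not pass camera in the main setting. In the heat shock and protein folding list 11 of 18 had a higher mean (adjusted p = 0.164), Hspe1 was called, and 2 passed over the list alone, Hspe1 and the cold-inducible Cirbp (-0.80, adjusted p = 0.152). Glucocorticoid response genes had 10 of 18 higher means (adjusted p = 0.625), with Angptl4 at 0.58 ± 0.32 (SE) and Per1 the 1 member to pass over the list alone. Immediate early genes had 8 of 18 higher means (adjusted p = 0.992), and Atf3 (-1.17 ± 0.74, SE) and Jun (-0.60 ± 0.26) varied more among the wild-type arrays (SD 1.84 and 0.64) than among the mutant ones (SD 0.54 and 0.17). Hypoxia and glycolysis genes had 11 of 15 higher means (adjusted p = 0.369), yet the 2 members that passed over the list alone had lower ones, the vasodilator peptide gene Adm (-0.60 ± 0.14, SE) and the glucose transporter Slc2a1 (-0.33). Hk2, a hexokinase, had a change of 0.36 ± 0.21 (SE). Interferon response genes had 4 of 14 higher means (adjusted p = 0.369), with the immunoproteasome subunits Psmb9 at -0.46 ± 0.25 (SE) and Psmb8 at -0.40 ± 0.21. Inflammation genes had 5 of 12 (adjusted p = 0.627), with Il1r1 at -0.34 ± 0.13 (SE) and S100a8 at -0.32 ± 0.25. Apart from Hspe1, 0 members of these lists were called by limma over all probe sets. At an unadjusted p of 0.05 there were 2 heat shock, 3 glucocorticoid, 3 immediate early, 3 hypoxia, 0 interferon and 1 inflammation gene. The heat shock list passed camera without wild type F16 (adjusted p = 0.00995), without mutant F13 (adjusted p = 0.0375), with the adipocyte covariate (adjusted p = 0.0400) and with the brown fat covariate (adjusted p = 0.00460), and the interferon list without wild type F11 (adjusted p = 0.0483). With an estimated correlation in the main setting the camera adjusted p was 0.813 for the heat shock and 0.892 for the interferon list.

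Housekeeping and biosynthetic lists did not pass in the main setting either. Cholesterol and fatty acid synthesis genes had 10 of 21 higher means, and the test pointed upwards (adjusted p = 0.850) while the median (-0.03) and mean (-0.01) were below 0, with Elovl6 at 0.52 ± 0.40 (SE) and Me1 at -0.31 ± 0.33. Haem metabolism genes had 9 of 14 (adjusted p = 0.369), with Alas1, the first enzyme of haem synthesis, at 0.26 ± 0.08 (SE) and Ppox at -0.31 ± 0.12. Cell cycle genes had 3 of 11 (adjusted p = 0.760), with Mcm3 at -0.25 ± 0.15 (SE) and Ccnd2 at -0.21 ± 0.12. Ribosomal protein genes had 6 of 19 (adjusted p = 0.572), with Rpl14 at -0.21 ± 0.26 (SE) and Rpl8 at -0.14 ± 0.06. Proteasome genes had 13 of 25 (adjusted p = 0.509), with Psmd12 at 0.17 ± 0.09 (SE) and Psma1 at 0.14 ± 0.06. These 5 lists had 0 members called by limma over all probe sets, and 1, 3, 0, 2 and 1 members, in the same order, at an unadjusted p of 0.05. Haem metabolism passed camera with the stricter filter (adjusted p = 0.0281) and ribosomal proteins without a filter, downwards (adjusted p = 0.0450), and with the brown fat covariate, upwards (adjusted p = 0.000749). Of the 27 lists tested, 6 passed camera with the preset correlation, 0 with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.146. For a change in either direction, fry passed 10 lists (adjusted p from 0.0140 to 0.0313). They were core clock, brown fat, fatty acid oxidation, contractile smooth muscle and adipocyte. The others were adrenergic and vasoactive, coagulation and fibrinolysis, heat shock and protein folding, glucocorticoid response, and hypoxia and glycolysis.

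Array controls of RNA quality were compared between the groups. The log2 difference between the 3' and 5' control probe sets of Gapdh was -0.08 ± 0.05 (SD, n = 5) in wild type and -0.07 ± 0.10 (SD, n = 5) in the mutant (exact two-sided permutation p = 0.873). For actin it was 0.93 ± 0.05 (SD, n = 5) and 1.01 ± 0.05 (SD, n = 5; exact permutation p = 0.0397), a small difference that moved with the groups. The 18S level did not separate them, with an exact permutation p of 0.690. The 3 controls were not adjusted for each other. Nnt, a mitochondrial transhydrogenase gene named beforehand because it differs between C57BL/6 substrains, had log2 levels of 7.58 ± 0.91 (SD, n = 5) in wild type and 6.84 ± 0.92 (SD, n = 5) in the mutant on probe set 1416105_at. Its change of -0.74 ± 0.50 (SE) had an adjusted p of 0.488, and on 1456573_x_at the change was -0.74 ± 0.44 (SE, adjusted p = 0.428).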

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

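The test of other splits of the arrays and the adipocyte covariate were planned, while the tests of skeletal muscle, brown fat and dilution below, and the use of the mean changes with the adipocyte covariate, were chosen after the calls had been seen.

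Of 100 sampled splits of the 10 arrays into 5 and 5, the real one included, 1 gave at least 48 called probe sets, the real one. The highest of the others gave 3, which argues against chance assignment of the arrays, though a test on 100 splits does not exclude it. With the skeletal muscle score as a covariate the mean change went from 0.84 ± 0.07 (SE) to 0.84 ± 0.07 for the probe sets that rose. For those that fell it went from -0.78 ± 0.04 to -0.78 ± 0.05. That the called probe sets do not follow this score was largely fixed in advance. They were picked on these arrays for separating the groups, while the score correlated with group at 0.287, so unequal skeletal muscle is not decided by it. Only 7 of the 48 calls were left. The standard errors grew (median ratio 1.08), residual degrees of freedom went from 8 to 7 and tested probe sets with limma p under 0.001 from 210 to 148. What each of these did to the calls was not separated. With the adipocyte score, whose planned bound on the median (0.1) was just missed at 0.102, 30 of the 48 calls remained. The mean changes went from 0.84 ± 0.07 (SE) to 0.83 ± 0.07 and from -0.78 ± 0.04 to -0.79 ± 0.05. This score correlated with group at 0.198 and could likewise hardly move probe sets picked for separation. Unequal perivascular fat is therefore not decided by it. Dilution of aortic transcripts by more brown fat, if even, would lower them alike. The 27 falls of smallest limma p were picked on 4 against 4 arrays and measured on the pair left out, over all 25 pairs. They changed by -0.48 ± 0.04 (SE), the contractile smooth muscle list by -0.15 ± 0.07 and the difference was -0.33 ± 0.08. This argues against even dilution as the whole cause of falls picked in this way (11 to 18 of the 27 were among the called ones). Members of that list changed unequally, such as Tpm1 (-0.36) and Des (0.48), so uneven dilution stays open. For the probe sets that rose, unequal brown fat stays open. Their mean change of 0.84 became 0.65 ± 0.09 (SE) with the brown fat score, which does not overlap between the groups and cannot be told apart from genotype. An effect of the Npas2 mutation itself, including on brown fat, is a candidate explanation that no test here separates. For all 48 called probe sets, the strain that the labels name differs along with the genotype. A strain difference therefore cannot be told apart from the mutation either.

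Values were compared within each group of 5 arrays by the ratio of the gap at the end to the range, and 19 of 254 such comparisons passed Dixon's 95% bound, where chance gives about 12.7. Among genes that changed, Ppa1 on wild type F15 stood at 9.15 against 9.50 to 9.55 on the other wild-type arrays, and Pisd-ps3 on wild type F17 at 5.91 against 6.76 to 6.96. Id4 on mutant F19 stood at 7.52 against 7.67 to 7.70, and the brightest Rgs5 probe set on mutant F18 at 12.38 against 11.89 to 12.01. Without mutant F18 that Rgs5 probe set had a change of -0.46 with an adjusted p of 0.0405.

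Among clock genes, Nr1d2 on mutant F20 stood at 9.33 against 9.78 to 9.94, and the core clock list mean of the same array at 5.90 against 6.07 to 6.13. Csnk1e on wild type F17 stood at 5.72 against 5.97 to 6.01. Ciart on wild type F15 stood at 3.12 against 2.70 to 2.75, and Bhlhe41 on wild type F14_2 at 2.59 against 2.40 to 2.45. Rorb on mutant F18 stood at 3.32 against 3.19 to 3.21, and the dimmer Npas2 probe set on wild type F17 at 2.22 against 2.39 to 2.43. The last 4 are near the lower end of the range.

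Among markers of other cells, Ighm on mutant F20 stood at 7.24 against 6.37 to 6.59, and the lymphocyte list mean of that array at 5.56 against 5.05 to 5.17. Ms4a1 on wild type F11 stood at 3.93 against 3.70 to 3.76, with the lymphocyte list mean at 5.22 against 4.91 to 4.97. Alas2 on wild type F17 stood at 6.57 against 7.87 to 8.28. Wild type F14_2 was low for Cd34, at 8.72 against 9.08 to 9.18, for the coagulation and fibrinolysis list, at 7.37 against 7.63 to 7.68, and for the inflammation list, at 5.55 against 5.78 to 5.83.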

How the results depend on the processing

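The brown fat covariate and the omission of the 4 arrays rich in skeletal muscle signal were chosen after the results had been seen. Genes and lists that passed neither in the main setting nor in an alternative were given no direction. The 48 calls (21 higher, 27 lower) became 17 (5 and 12, with 15 shared) without a filter on dim probe sets and 141 (51 and 90, with 38 shared) with the stricter filter, where fewer probe sets are adjusted for. They became 191 (54 and 137) at an adjusted p of 0.1 and 13 (5 and 8) by the ordinary one-way analysis, which does not pool the spread. The skeletal muscle score left 7 (2 and 5), the brown fat score 1 (1 and 0, with 0 shared and 1800 at an unadjusted p of 0.05) and the omission of 4 arrays 0 (0 and 0), with fewer arrays. Those higher numbered 32 after quantile normalisation, 34 after median centring and 13 with the adipocyte score, and the cause was not tested. Leaving out 1 array gave 9 to 43 calls, 2 to 13 higher and 6 to 30 lower. Median centring moved the median change of all probe sets by 0.06.

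Npas2 kept its side of the threshold and its direction under every alternative that tested it, from -0.34 to -0.22 when 1 array was left out. Of 92 named genes and probe sets 25 were called, and 0 of these turned in sign, while 24 of the other 67, which have no call, did so under some alternative. All 25 were lost with the brown fat score or without the 4 arrays, 21 with the skeletal muscle score, 20 without a filter, 9 with the adipocyte score, 4 after median centring, 2 with array weights, 1 after quantile normalisation and 11 to 21 when 1 array was left out. Elovl3 was called with the stricter filter (adjusted p = 0.0484).

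All 6 lists called by camera lost the call with an estimated correlation, at adjusted p = 0.699 (brown fat, macrophage and leukocyte, fatty acid oxidation), 0.773 (contractile smooth muscle, oxidative phosphorylation) and 0.813 (skeletal muscle). With fry the adjusted p was 0.146 (brown fat, fatty acid oxidation), 0.219 (contractile smooth muscle), 0.247 (macrophage and leukocyte), 0.295 (oxidative phosphorylation) and 0.773 (skeletal muscle), where the null hypothesis differs as well. The skeletal muscle list also lost it without a filter (0.182), after quantile normalisation (0.0618) and median centring (0.190), and ranged from 2.53e-06 to 0.238 when 1 array was left out. Without the 4 arrays it reversed (0.00412). With the brown fat score contractile smooth muscle lost the call (0.193), and the lists of skeletal muscle (0.437), fatty acid oxidation (0.00743), oxidative phosphorylation (2.62e-12), extracellular matrix (0.0199) and ribosomal proteins (0.000749) reversed. The camera direction of the adventitial fibroblast list turned upwards too (0.000206), though its median was above 0 in both. The cause was not tested. Of the lists not called, 10 gained a call under some alternative. Pseudocounts did not apply to log2 values and were not run. Npas2, Arntl, Ciart, Nr1d1 and Rorb lie near background, which limits what can be said of them.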

Other observations

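The neighbourhood of Npas2 and its test were planned, and the tests on Nnt were chosen after its values had been seen.

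Wild type F16 was among the 4 arrays with a skeletal muscle mean above 8, yet its levels of the fast myosin genes Myh1 (5.68) and Myh2 (3.18) lay below those of wild type F14_2 (6.82 and 6.44), which was not. Among the tested probe sets, the most variable named transcripts within groups were troponin genes of fast skeletal muscle, Tnnc2, Tnni2 and Tnnt3. Their standard deviations were 4.02, 3.96 and 3.75 on the log2 scale. The muscle creatine kinase gene Ckm (3.69) and the fast myosin gene Myh4 (3.62) followed. Probe sets too dim to be tested were not ranked.

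A targeted allele moved onto another background can carry flanking DNA of the donor strain, so genes near Npas2 may differ for that reason. Of 118 tested genes within 20 Mb of Npas2 1 was called, Hspe1, against 29 of 10826 others (odds ratio 3.18, 95% interval 0.0773 to 19.5, Fisher's exact p = 0.278). At an adjusted p of 0.1 the counts were 3 (Hspe1, Ankrd44 and AI597479) and 129 (Fisher's exact p = 0.171), and within 10 Mb 0 of 63 genes were called. A call on a single gene decides nothing, and the hypothesis of donor DNA stays open for Hspe1.

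Nnt varied widely inside both groups. On wild-type arrays F11, F14_2, F15, F16 and F17 probe set 1416105_at stood at 7.77, 8.16, 8.36, 7.54 and 6.06, and on mutant arrays F12, F13, F18, F19 and F20 at 8.26, 7.19, 5.93, 6.28 and 6.52. Its within-group standard deviation was 2.96 times the largest in the oxidative phosphorylation list, that of Uqcrc1 (0.91 against 0.31), but inside the groups Nnt followed the mean of that list and the brown fat mean, so unequal mitochondrial or brown fat content of the pieces stays open. Of the mutant arrays 4 lay inside the wild-type range. Nnt followed the brown fat mean, which was higher in the mutant, so this overlap does not decide on a fixed difference between the named strains. Over the alternatives the change of Nnt on 1416105_at ran from -2.90 to -0.51, and it was called in none (smallest limma adjusted p = 0.0965). The -2.90 came with the brown fat score as a covariate. That score does not overlap between the groups, so the larger change neither shows nor excludes a difference between the named strains. An Nnt allele that differed among animals of both groups may also explain part of the spread inside the groups, as a hypothesis. The animals' Nnt genotype was not analysed here.

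The probe sets 1416105_at and 1456573_x_at of Nnt varied together over the 10 arrays, with Pearson's r of 0.978 (permutation p = 1e-05, the smallest these permutations can give, adjusted 4e-05) and Spearman's rho of 0.964 (permutation p = 5e-05, adjusted 0.0002). Without the 2 arrays farthest from the median r was 0.981. The other 3 relations of this family of 4 did not pass over all 10 arrays. Nnt against the skeletal muscle mean gave r = 0.228 (permutation p = 0.514, adjusted 0.685) and rho = 0.455 (p = 0.191, adjusted 0.382), and r = -0.0754 without the 2 farthest arrays. Nnt against the oxidative phosphorylation mean gave r = 0.400 (permutation p = 0.247, adjusted 0.494) and rho = 0.309 (p = 0.387, adjusted 0.516), and r = 0.265 without them. Nnt against the brown fat mean gave r = 0.131 (permutation p = 0.712) and rho = 0.0424 (p = 0.918), and r = -0.178 without them. Inside the groups, with each value taken less its group mean and permuted inside its group in all 14400 ways, the relation to the brown fat mean had r = 0.910 (permutation p = 0.00111, adjusted 0.00222) and rho = 0.850 (p = 0.00931, adjusted 0.0124), and r = 0.818 without the 2 farthest arrays. By group r was 0.890 in wild type and 0.940 in the mutant. For the oxidative phosphorylation mean r was 0.849 (permutation p = 0.00604, adjusted 0.00806) and rho 0.850 (p = 0.00931, adjusted 0.0124), and r = 0.862 without the 2 farthest, with 0.763 in wild type and 0.927 in the mutant. For the skeletal muscle mean r was 0.397 (permutation p = 0.295, adjusted 0.295) and rho 0.5 (p = 0.192, adjusted 0.192), and r = 0.350 without the 2 farthest. The probe sets of Nnt gave r = 0.975 (adjusted p = 0.00111) inside the groups.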
